A study of Mus musculus with 16 samples.

How the data were processed

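The series measured RNA of sorted mouse liver cells. Per the labels' protocols, livers of mice aged 4 weeks were digested with collagenase and DNase, cholangiocytes were sorted with the lectin DBA, and RNA was isolated with RNeasy columns. RNA with an integrity number above 7 was pooled in equal amounts over 6 to 8 mice per genotype with equal numbers of each sex. Libraries were made with a NEBNext kit with ribosome reduction and sequenced on a NextSeq500 with paired-end 75 nt reads. Per the submitters' processing notes, bcl2fastq 2.18.0.12, STAR, HTSeq and Cufflinks 2.2.1 with Cuffdiff were used on the GRCm38.p4 build. The authors' counts are raw reads per Ensembl gene from HTSeq-count 0.9.1. Versions of STAR and HTSeq's strand setting and annotation release are not given in the sources used here. The authors' FPKM values and their own differential tests were not used here.

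The deposited counts held 48795 gene identifiers, 48349 of which matched a symbol and position in the GENCODE annotation, and 5 summary lines. In the 16 libraries 44.75 to 57.28% of the counted reads lay in genes, 29.08 to 45.18% (median 39.44%) in no feature, 2.23 to 3.95% were ambiguous and 7.02 to 11.18% were not uniquely aligned. Gene counts totalled 10170795 to 26093556 per library. The 10 most counted genes took 10.84 to 28.04% of gene counts, and mitochondrial genes 2.64 to 14.75%. CPM values were scaled with TMM factors.

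Groups followed the labels: 2 strains, 2 genotypes and 4 populations, with 1 library in each of the 16 groups. The labels number no replicates, and libraries of 1 strain and genotype may share mice. Ly6Chi was compared with Ly6Clo macrophages in their 8 libraries with the strain and genotype combination as a block. Genotype and strain were tested within each population in a fit of all 16 libraries with terms for population, population by strain and population by genotype, which takes the other factor's levels as replicates. A strain by genotype term shared by the populations was added for its own test. The strain by macrophage type and genotype by macrophage type terms were contrasts of this same fit, with the strain by genotype term included. Within 1 strain and population, pairs of single libraries gave log2 ratios of CPM with a pseudocount of 1 CPM and no test.

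Genes were filtered with edgeR's filterByExpr and tested with edgeR 4.0.16 (quasi-likelihood test, R 4.3.3) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adjusted p values of genes come from this test unless DESeq2 1.42.0 is named. SE is the log2 fold change over the square root of the F statistic. The 38 gene lists (13 of cell type markers, 25 of processes) were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Their adjusted p values are over the lists of a comparison, and lists with fewer than 4 tested genes were left out. Counts "over the list alone" adjust gene p values within the list. In pairs, list medians were ranked among 10000 random lists matched on 20 expression bins. Ratios carry 95% counting intervals from the exact binomial, and a library or group at 0 was set to 3 counts for a lower bound, over the group in tests and per library in pairs. Log2 ratios used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. BLAST 2.17.0 found copies of ribosomal protein genes (at least 95% identity over 150 bases).

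The comparisons, lists, named-gene rule and most alternatives were fixed before the data were examined. For Ly6Chi against Ly6Clo macrophages the rule named the 12 largest and 12 smallest fold changes among called genes with at least 10 CPM in the higher group and 1 direction in all 4 combinations. For strain and genotype it named 10 and 10 with 1 direction in both levels of the other factor, and for the terms of difference 6 and 6. For pairs it named 5 and 5 per population by the difference of log2 ratios between strains, with at least 20 CPM in 1 of the 4 libraries and an absolute log2 ratio of 1 in 1 strain. Predicted genes, antigen receptor segments, mitochondrial genes, Xist and Y-linked genes were skipped. A gene that the rule named for pairs is not reported here. List members are given as examples, at most 6 per list, in order of p. Ift88, strain and sex markers, Gm26917 and the monocyte genes in neutrophils were named outside the rule, the last 2 after their values were seen.

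Alternatives were relative log expression and upper-quartile factors, no filter beyond a total of 1 count, a filter of 5 CPM in 2 libraries and DESeq2. Others were leaving out each library or combination in turn, fits of 1 population or of the 8 macrophage libraries, no block, and an added strain by genotype term. For pairs they were pseudocounts of 0.25 and 5 CPM, minimums of 20 CPM or none, and other scalings, and for lists fry, an estimated correlation, relative log expression scaling and removal of members shared with other marker lists. Fits without Gm26917, Lars2 and mitochondrial genes, and without pseudogene-type and ribosomal protein genes, were chosen after seeing the data.

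The tests were tried on simulated data with known changes. For Ly6Chi against Ly6Clo macrophages (16120 genes) edgeR recovered 86.5% of genes changed 2-fold and 100% of those changed 4-fold, with 12 false calls among 199; DESeq2 recovered 85.4% and 100%, with 18 false among 204. For genotype in DBA-sorted cells (20553 genes) the shares were 5.3% and 66.7% with 1 false among 76, against 8.4% and 70.5% with 7 among 89 for DESeq2. For strain in neutrophils (20597 genes) they were 6.3% and 67.6% with 1 false among 78, against 11.6% and 72.4% with 11 among 98. For lists, simulated for Ly6Chi against Ly6Clo macrophages alone, camera with the preset correlation called the changed list and 0 of the unchanged lists, while the estimated correlation missed it. Of 40 unchanged lists in a simulated pair, 2 lay outside percentiles 2.5 to 97.5, and a shifted list lay at 98.93. Genes were drawn independently in these simulations, so they do not show how either list method behaves when members move together.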

Results

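The series held 16 RNA-seq libraries of liver cells from mice aged 4 weeks. Each library was made from RNA pooled over 6 to 8 mice. The libraries covered 2 strains (C57BL/6 and BALB/c), 2 genotypes (wild type and Ift88Orpk) and 4 sorted populations: DBA-sorted cells labelled cholangiocytes, Ly6Chi and Ly6Clo infiltrating macrophages, and neutrophils. There was 1 library per combination of strain, genotype and population. In each library 18357 to 21962 genes had at least 1 count. Strains served as the replicates of a genotype comparison within a population, and genotypes as the replicates of a strain comparison.

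Ift88 (ENSMUSG00000040040, chromosome 14, 57424062 to 57517936), which encodes an intraflagellar transport protein, was counted in all 16 libraries. In the DBA-sorted cells it was at 8.78 CPM in wild type and 7.63 CPM in Ift88Orpk of C57BL/6 (ratio 0.87, 95% counting interval 0.694 to 1.09), and at 8.59 and 4.62 CPM in BALB/c (0.538, 0.415 to 0.693). In Ly6Chi macrophages the values were 1.44 and 3.85 CPM in C57BL/6 (2.68, 1.59 to 4.8) and 4.31 and 5.85 CPM in BALB/c (1.36, 0.995 to 1.85). In Ly6Clo macrophages they were 3.92 and 4.01 CPM (1.02, 0.761 to 1.39) and 3.2 and 4.5 CPM (1.4, 1.02 to 1.95). In neutrophils they were 2.75 and 7.01 CPM (2.54, 1.6 to 4.22) and 1.99 and 8.72 CPM (4.37, 2.94 to 6.62). Reads summed over the gene do not separate the Orpk insertion allele from the intact one, and groups are therefore called by their label, Ift88Orpk. Counting intervals cover the sampling of reads alone, not the difference between pools of mice.

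The sorted populations differed in their leading cell type markers. In the 4 DBA-sorted libraries, 11 sinusoidal endothelial markers (Stab2, Kdr and others) summed to 20900 ± 3780 CPM (mean ± SD, n = 4), 12 cholangiocyte markers (Krt7, Krt19, Epcam and others) to 680 ± 238 CPM, hepatocyte markers to 2940 ± 922 CPM, and stellate cell and fibroblast markers to 4460 ± 3580 CPM. Cholangiocyte markers were at 18.8 ± 7.43 CPM in Ly6Chi macrophages, 31.4 ± 5.98 CPM in Ly6Clo macrophages and 91.4 ± 3.95 CPM in neutrophils. Neutrophil libraries held 23400 ± 4840 CPM of neutrophil markers, 4760 ± 1270 CPM of Ly6Chi monocyte markers, 3500 ± 1290 CPM of hepatocyte markers, 1740 ± 1320 CPM of sinusoidal endothelial markers and 1510 ± 372 CPM of Kupffer cell markers. Hepatocyte markers were at 1540 ± 601 CPM in Ly6Chi and 1130 ± 508 CPM in Ly6Clo libraries. Ly6Chi monocyte markers summed to 7710 ± 1040 CPM in Ly6Chi and 1560 ± 636 CPM in Ly6Clo libraries. Markers of T and NK cells were at 753 ± 377 CPM in Ly6Clo against 77.2 ± 74.4 CPM in Ly6Chi libraries, and dendritic cell markers at 536 ± 182 against 65.8 ± 36 CPM. Erythroid markers reached 181 ± 100 CPM in neutrophils, and eosinophil, basophil and mast cell markers 60.2 ± 35.7 CPM.

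**Figure D1:**
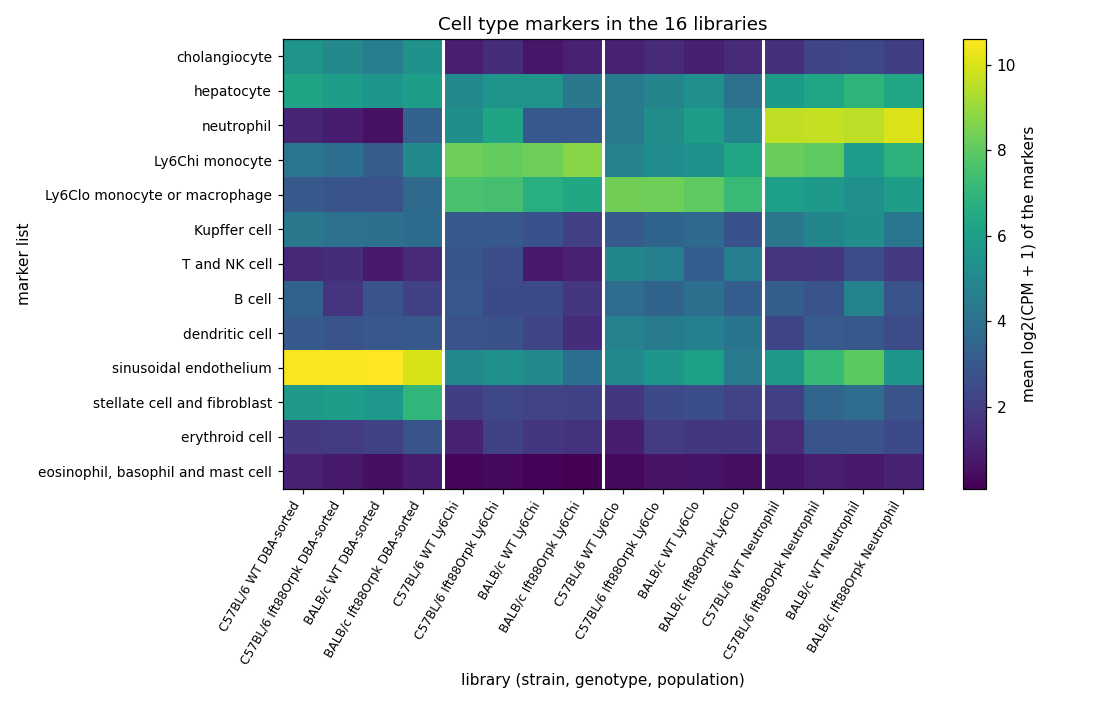
Cell type markers in the 16 libraries, as the mean log2(CPM + 1) of each marker list (colour) per library (strain, genotype and population, n = 1 each). Endothelial markers lead in the 4 DBA-sorted libraries.

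Ly6Chi and Ly6Clo macrophages differed in a large part of their transcriptome. Ly6Chi cells carried the classical monocyte programme together with higher interferon-stimulated, inflammatory, glycolytic and respiratory chain transcripts. Ly6Clo libraries held higher cell cycle, MHC class II, dendritic cell and lymphocyte transcripts, whose source among the sorted cells was not tested. None of these list calls held with an estimated correlation (adjusted p = 0.227 to 0.705 with an estimated correlation). Of 16664 genes tested with edgeR's quasi-likelihood test, 4075 passed a Benjamini-Hochberg adjusted p of 0.05, 2047 higher and 2028 lower in Ly6Chi cells. Unadjusted p was below 0.05 for 5984 genes, and DESeq2 called 4644. Without the block for strain and genotype the count was 1861, and with all 16 libraries and the block it was 1467.

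The largest rises in Ly6Chi cells included Vcan, F13a1, Fn1 and Thbs1. Vcan, the proteoglycan versican, rose by 5.72 ± 0.79 log2 units (± SE; 204 ± 130 against 9.43 ± 16.9 CPM, adjusted p = 0.0013; 0.0774 without the block). F13a1, the A subunit of coagulation factor XIII, rose by 4.32 ± 0.42 (596 ± 133 against 37.7 ± 29.1 CPM, adjusted p = 0.000239). Fn1, fibronectin, rose by 3.61 ± 0.40 (2300 ± 1270 against 280 ± 329 CPM, adjusted p = 0.000443), and Thbs1, thrombospondin 1, by 3.58 ± 0.29 (1220 ± 635 against 139 ± 153 CPM, adjusted p = 0.000102). Saa3, an acute-phase serum amyloid, rose by 5.17 ± 0.51 (adjusted p = 0.000274). The sorted antigen itself parted the groups: Ly6c2 rose by 4.55 ± 0.32 (261 ± 28 against 11.8 ± 5.67 CPM, adjusted p = 5.59e-05) and Ly6c1 by 4.79 ± 0.35 (55.7 ± 64.8 against 2.28 ± 3.42 CPM, adjusted p = 6.36e-05; 0.18 without the block and 0.0505 with all 16 libraries). Ms4a8a, a membrane-spanning 4-domain protein, rose by 3.90 ± 0.35 (adjusted p = 0.000181). Signalling and lipid enzymes rose as well: Plcb1, phospholipase C beta 1, by 3.34 ± 0.10 (adjusted p = 3.08e-06), Sgms2, sphingomyelin synthase 2, by 2.85 ± 0.17 (adjusted p = 3.01e-05), and the small GTPase Rab36 by 2.74 ± 0.17 (adjusted p = 3.89e-05). Lars2, mitochondrial leucyl-tRNA synthetase, rose by 2.72 ± 0.73 (285 ± 276 against 26 ± 5.8 CPM, adjusted p = 0.0278). This last call was lost without the C57BL/6 wild type libraries (0.0689), without the C57BL/6 Ift88Orpk libraries (0.134) and with all 16 libraries (0.124).

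Genes lower in Ly6Chi than in Ly6Clo cells included the C-type lectins Mgl2 and Cd209b and the receptors Klri1 and Il1rl1. Ctnnd2, delta-catenin, changed by -6.37 ± 0.52 log2 units (0.457 ± 0.707 against 36.5 ± 20 CPM, adjusted p = 0.000105), and Klri1, a killer cell lectin-like receptor, by -6.19 ± 0.25 (0.52 ± 0.283 against 36.9 ± 9.34 CPM, adjusted p = 9.47e-06). The C-type lectins Mgl2 (CD301b) and Cd209b changed by -5.32 ± 0.60 (adjusted p = 0.000491) and -4.86 ± 0.72 (adjusted p = 0.00177). Cd7, a T and NK cell glycoprotein, changed by -4.95 ± 0.42 (adjusted p = 0.00013), and Il1rl1, the interleukin 33 receptor ST2, by -4.85 ± 0.35 (adjusted p = 6.36e-05). Further falls were seen for the kinase Stk32c (-4.85 ± 0.48, adjusted p = 0.000262), the calcium channel subunit Cacnb3 (-4.72 ± 0.55, adjusted p = 0.00056) and the ubiquitin ligase subunit Asb2 (-4.70 ± 0.34; 2.34 ± 0.593 against 67.4 ± 34.3 CPM, adjusted p = 6.36e-05). Ffar2, a receptor for short-chain fatty acids, changed by -4.59 ± 0.26 (adjusted p = 2.37e-05), the ETS factor Ehf by -4.58 ± 0.34 (adjusted p = 6.76e-05) and Adgrl3, latrophilin 3, by -4.58 ± 0.30 (adjusted p = 4.22e-05).

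**Figure D2:**
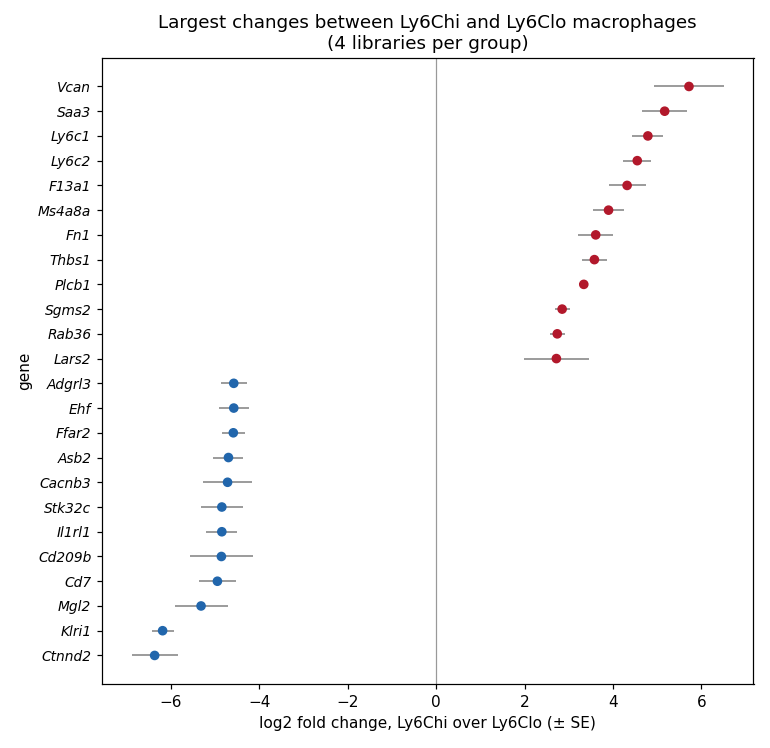
Log2 fold change (± SE) of Ly6Chi over Ly6Clo macrophages for the 12 most raised and 12 most lowered genes, with 4 libraries per group. Values ran from -6.37 (Ctnnd2) to 5.72 (Vcan).

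As gene lists, interferon-stimulated genes were higher in Ly6Chi cells (37 of 39 called higher and 39 over the list alone, camera adjusted p = 8.74e-19; adjusted p = 0.369 with an estimated correlation). Gbp2 (1.68 ± 0.08, adjusted p = 1.63e-05), Ifi27l2a (1.63 ± 0.09), Oas3 (1.22 ± 0.08) and Gbp5 (1.63 ± 0.12) led it. The 11 Ly6Chi monocyte markers were higher (10 called and 11 over the list alone, adjusted p = 2.86e-08; adjusted p = 0.369 with an estimated correlation), among them Plac8 (2.05 ± 0.09), Hp (1.93 ± 0.13) and Ccr2 (1.56 ± 0.12), the chemokine receptor of monocyte egress. Of 29 inflammatory cytokines and NF-kB targets, 16 were called higher and 1 lower (adjusted p = 0.000405; adjusted p = 0.369 with an estimated correlation), with Tnfaip2 at 1.96 ± 0.12 and oncostatin M (Osm) at 1.61 ± 0.14. Oxidative phosphorylation genes were higher (19 of 36 called and 25 over the list alone, adjusted p = 2.86e-08; adjusted p = 0.227 with an estimated correlation), with Uqcrfs1 at 0.73 ± 0.09 and Cox4i1 at 0.61 ± 0.08. Glycolysis and hypoxia genes were higher (15 called higher and 2 lower of 30, adjusted p = 0.000556; adjusted p = 0.705 with an estimated correlation), with Ndrg1 at 1.88 ± 0.15 and Pkm at 0.79 ± 0.09. Cytosolic ribosomal protein genes were higher by a smaller step (17 of 36 called, adjusted p = 1.86e-05; adjusted p = 0.705 with an estimated correlation), with Rps9 at 0.57 ± 0.07.

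Cell cycle genes were lower in Ly6Chi cells (39 of 40 called lower and 40 over the list alone, adjusted p = 8.74e-19; adjusted p = 0.369 with an estimated correlation). The replication licensing genes Mcm5 (-2.04 ± 0.11, adjusted p = 2.37e-05), Mcm2 (-2.13 ± 0.12) and Mcm7 (-1.53 ± 0.11) led the list. MHC class II presentation was lower (10 called lower and 1 higher of 13, adjusted p = 0.000157; adjusted p = 0.369 with an estimated correlation), with H2-Ob at -4.34 ± 0.15, H2-Oa at -4.57 ± 0.25, H2-Ab1 at -1.66 ± 0.16 and the protease Ctss at 0.79 ± 0.07. Dendritic cell markers (8 of 10 called lower, adjusted p = 2.45e-06; adjusted p = 0.369 with an estimated correlation) moved with it: Zbtb46 -3.71 ± 0.15, Ccr7 -3.67 ± 0.15 and Flt3 -2.87 ± 0.19. T and NK cell markers were lower (8 of 11 called and 9 over the list alone, adjusted p = 5.47e-05; adjusted p = 0.369 with an estimated correlation), with Cd4 at -4.07 ± 0.17, Klrb1c at -3.85 ± 0.45 and Ncr1 at -4.43 ± 0.67. B cell markers were lower (7 of 8 called and 8 over the list alone, adjusted p = 0.00021; adjusted p = 0.369 with an estimated correlation), with Cd22 at -2.70 ± 0.18. The 11 markers of Ly6Clo monocytes were lower (7 called, adjusted p = 0.00931; adjusted p = 0.546 with an estimated correlation), with Cd300e at -3.97 ± 0.39 and Pparg at -1.24 ± 0.15.

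Smaller list differences followed. Hepatocyte markers were higher in Ly6Chi cells (6 of 12 called and 9 over the list alone, adjusted p = 0.000792; adjusted p = 0.705 with an estimated correlation), with albumin (Alb) at 0.43 ± 0.11. Matrix proteases and inhibitors were higher (11 called higher and 2 lower of 26, adjusted p = 0.0308; adjusted p = 0.705 with an estimated correlation; 0.0593 and 0.106 without the C57BL/6 Ift88Orpk or wild type libraries). Xenobiotic and glutathione genes were higher (4 of 19 called, adjusted p = 0.015; adjusted p = 0.7 with an estimated correlation; 0.0561 without members of other lists), with Mgst1 at 1.99 ± 0.13 and glutathione reductase (Gsr) at 0.99 ± 0.08. Kupffer cell markers were lower (2 of 10 called, Cd163 -1.91 ± 0.22 and Timd4 -1.55 ± 0.39, adjusted p = 0.0404; adjusted p = 0.705 with an estimated correlation), as were endothelial markers (2 of 11 called and 3 over the list alone, adjusted p = 0.031; adjusted p = 0.836 with an estimated correlation). The Kupffer cell call was lost without the C57BL/6 Ift88Orpk (0.0593) or BALB/c wild type libraries (0.209), and the endothelial call without the BALB/c Ift88Orpk (0.0642) or wild type libraries (0.313). The other lists were not called: neutrophil granule genes (adjusted p = 0.173), lipid- and scar-associated macrophage genes (0.249; 9 called higher and 6 lower), and alternative activation (0.402; 5 higher and 10 lower). Nor were Hedgehog, Notch and erythroid genes (0.514 each), YAP and TEAD targets and neutrophil markers (0.602 each), bile secretion (0.622), efferocytosis (0.649), profibrotic ligands (0.689) and unfolded protein response (0.737). The remaining lists were chemokines (0.743), immediate early genes (0.765), and cholangiocyte and stellate cell markers, cilium, cystic disease, extracellular matrix and cholesterol genes (0.835 each). Within the uncalled lists, Lgals3, galectin 3, rose (1.33 ± 0.07, adjusted p = 2.2e-05), while the fatty acid transporter Cd36 (-1.62 ± 0.12, adjusted p = 6.87e-05) and Fabp4 (-2.62 ± 0.29, adjusted p = 0.000479) fell. Clec10a fell (-2.05 ± 0.10, adjusted p = 1.26e-05) and Msr1 rose (1.89 ± 0.19).

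No single gene passed the test between Ift88Orpk and wild type in any of the 4 populations, with both strains taken as replicates. Lists of related genes did differ by camera's preset correlation, and the 4 populations shared some of these: glycolysis and hypoxia genes were higher and B cell markers lower in each. These 8 calls ended with an estimated correlation (adjusted p = 0.778 to 0.981 with an estimated correlation), and only in Ly6Chi macrophages did both hold whichever library was left out. The mitochondrial share of gene counts was lower in Ift88Orpk than in wild type in all 6 leukocyte pairs: in C57BL/6 and BALB/c, 9.56 to 5.97% and 6.66 to 2.98% in Ly6Chi macrophages, 7.67 to 5.55% and 4.78 to 2.64% in Ly6Clo macrophages, and 7.74 to 5.22% and 11.05 to 3.15% in neutrophils. In DBA-sorted cells it went from 14.75 to 8.26% and from 5.39 to 12.4%. Of 21534 genes tested with edgeR's quasi-likelihood test, 0 were called in any population. Unadjusted p was below 0.05 for 1140 genes in DBA-sorted cells, 408 in Ly6Chi macrophages, 348 in Ly6Clo macrophages and 934 in neutrophils. DESeq2 called 83, 3, 11 and 26 genes in the same order. In DBA-sorted cells 48 genes were called without the C57BL/6 wild type library, 47 without the C57BL/6 Ift88Orpk library, and 0 without either BALB/c library. Gene values given for the genotype lists are fitted log2 fold changes ± SE of genes that did not pass. Xist and Y-linked genes differed with genotype in each C57BL/6 population, so these comparisons do not part genotype from the sex balance of the pools.

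In the DBA-sorted cells, extracellular matrix genes were among the 11 lists called. Of 35 members, 34 had positive values (median 1.34, camera adjusted p = 0.00025; adjusted p = 0.981 with an estimated correlation), and 1 was called over the list alone. The contractile genes Acta2 (2.01 ± 0.39, gene-level adjusted p = 0.441) and Tagln (1.36 ± 0.39, 0.733) and the collagens Col15a1 (1.75 ± 0.47, 0.697) and Col6a2 (1.83 ± 0.64, 0.836) led them. Inflammatory genes were higher (29 of 31 positive, median 0.64, adjusted p = 0.000329; adjusted p = 0.981 with an estimated correlation), with Tnf at 2.25 ± 0.53, Ptgs2 at 2.56 ± 0.65 and Il1b at 2.02 ± 0.59. Lipid- and scar-associated macrophage genes (19 of 22 positive, median 0.57, adjusted p = 0.00207; adjusted p = 0.981 with an estimated correlation) included Gpnmb (3.15 ± 0.87), Cd63 (1.54 ± 0.32) and Trem2 (2.35 ± 0.87). Neutrophil markers (12 of 12 positive, median 2.29, adjusted p = 0.00207) moved with them, as did neutrophil granule genes (19 of 20 positive, median 1.66, adjusted p = 0.00025) and Ly6Chi monocyte markers (9 of 11 positive, median 1.08, adjusted p = 0.0222). Each of these 3 lists had an adjusted p = 0.981 with an estimated correlation. Glycolysis and hypoxia genes (29 of 31 positive, median 0.42, adjusted p = 0.000855), ribosomal protein genes (35 of 36, median 0.32, adjusted p = 0.000892), matrix proteases (adjusted p = 0.0275) and chemokines (adjusted p = 0.0337) were higher. B cell markers were lower (0 of 8 positive, median -1.39, adjusted p = 4.37e-06; Cd79a -2.13 ± 0.57, Ighm -1.35 ± 0.37). Each of these 5 lists also had an adjusted p = 0.981 with an estimated correlation. Ribosomal protein genes kept the call whichever library was left out. B cell markers (0.0804 and 0.0805) and glycolysis genes (0.257 and 0.274) lost it without either C57BL/6 library, lipid- and scar-associated genes without any 1 of the 4 (0.0687 to 0.169), and the other 7 lists without either BALB/c library (0.272 to 0.823). For neutrophil markers, granule genes and Ly6Chi monocyte markers the sign turned without either BALB/c library: their medians were -0.56, -0.25 and -0.56 in the C57BL/6 pair and 3.22, 2.32 and 1.75 in the BALB/c pair. Cilium genes were not called; Ift52 was at -0.94 ± 0.25 (gene-level adjusted p = 0.677).

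In Ly6Chi macrophages, glycolysis and hypoxia genes gave the lowest list p (29 of 31 positive, median 0.52, adjusted p = 4.46e-11; adjusted p = 0.778 with an estimated correlation). Vegfa, vascular endothelial growth factor A, was at 2.82 ± 0.78, the glucose transporters Slc2a3 and Slc2a1 at 1.35 ± 0.41 and 1.13 ± 0.38, and the prolyl hydroxylase Egln3 at 1.88 ± 0.58, with gene-level adjusted p = 1 for each. Immediate early genes were higher (21 of 33 positive, median 0.21, adjusted p = 0.000362; adjusted p = 0.778 with an estimated correlation), with Egr1 at 1.56 ± 0.34 and Fosb at 1.37 ± 0.32, and 2 called over the list alone. Inflammatory genes (24 of 31 positive, median 0.47, adjusted p = 0.000839), matrix proteases (adjusted p = 0.000839; Adam8 1.40 ± 0.38, Ctsl 0.88 ± 0.31), and lipid- and scar-associated genes (adjusted p = 0.00175) were higher. So were cholangiocyte markers (11 of 12 positive, median 1.20, adjusted p = 0.00175), efferocytosis genes (adjusted p = 0.0223) and profibrotic ligands (adjusted p = 0.0446). B cell markers (1 of 8 positive, median -0.70, adjusted p = 0.000839), dendritic cell markers (adjusted p = 0.0329) and cholesterol synthesis genes (median -0.26, adjusted p = 0.0225) were lower. These 9 lists each had an adjusted p = 0.778 with an estimated correlation. Interferon-stimulated genes were slightly lower (10 of 39 positive, median -0.18, adjusted p = 0.0137; adjusted p = 0.817 with an estimated correlation), with Cmpk2 at -0.69 ± 0.25 and Mx2 at -0.57 ± 0.21. Glycolysis, immediate early, inflammatory and protease genes and B cell markers kept the call whichever library was left out. Cholangiocyte markers, profibrotic ligands and cholesterol genes lost it without either C57BL/6 library (0.136 to 0.662), and the other 4 lists without either BALB/c library (0.056 to 0.717).

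In Ly6Clo macrophages, lipid- and scar-associated macrophage genes gave the lowest list p (17 of 22 positive, median 0.45, adjusted p = 3.1e-06; adjusted p = 0.288 with an estimated correlation), and 6 were called over the list alone. Osteopontin (Spp1, 1.65 ± 0.36), the cholesterol exporter Abca1 (1.65 ± 0.38), Cd63 (1.38 ± 0.32), Apoe (1.15 ± 0.34) and the lipid receptor Trem2 (2.23 ± 0.67) led it, with gene-level adjusted p = 1 for each. Efferocytosis and complement genes (17 of 23 positive, median 0.77, adjusted p = 9.51e-05; adjusted p = 0.881 with an estimated correlation) included C1qa (1.87 ± 0.47), C1qb (1.76 ± 0.52) and the receptor kinase Mertk (1.76 ± 0.53). Matrix proteases (26 of 30 positive, median 0.43, adjusted p = 8.92e-05; adjusted p = 0.871 with an estimated correlation) included Mmp14 (1.69 ± 0.49) and Timp2 (0.97 ± 0.32). Extracellular matrix genes (29 of 35 positive, median 0.52, adjusted p = 0.00114; adjusted p = 0.97 with an estimated correlation) and profibrotic ligands (adjusted p = 0.0141; adjusted p = 0.881 with an estimated correlation; Pdgfa 2.52 ± 0.87) were higher. So were chemokines (adjusted p = 0.0174; adjusted p = 0.882 with an estimated correlation) and glycolysis genes (median 0.23, adjusted p = 0.00944; adjusted p = 0.97 with an estimated correlation). Markers of Ly6Chi monocytes (median 0.63, adjusted p = 0.0247; adjusted p = 0.97 with an estimated correlation), cholangiocytes (median 0.95, adjusted p = 0.00158; adjusted p = 0.881 with an estimated correlation) and erythroid cells (median 1.02, adjusted p = 0.0176) were higher. Markers of Ly6Clo monocytes (median -0.48, adjusted p = 0.0174), B cells (median -0.62, adjusted p = 0.00634) and hepatocytes (median -0.48, adjusted p = 0.0419; adjusted p = 0.981 with an estimated correlation) and cell cycle genes (median -0.21, adjusted p = 0.0174; adjusted p = 0.981 with an estimated correlation) were lower. The markers of Ly6Clo monocytes, B cells and erythroid cells each had an adjusted p = 0.97 with an estimated correlation. Only the lipid- and scar-associated list kept its call whichever library was left out. Hepatocyte, Ly6Clo monocyte and B cell markers and cell cycle genes lost it without either BALB/c library (0.121 to 0.62), Ly6Chi monocyte markers and glycolysis genes without any 1 of the 4 (0.0741 to 0.181), and the other 7 lists without either C57BL/6 library (0.0755 to 0.92). The sign turned with the loss for hepatocyte (0.53 in the C57BL/6 and -1.52 in the BALB/c pair) and erythroid markers (1.60 and -0.15). Extracellular matrix genes also had pair medians of opposite sign, at 1.13 (percentile 100 among random lists) in C57BL/6 and -0.24 (percentile 1.62) in BALB/c.

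In neutrophils, glycolysis and hypoxia genes were higher (28 of 31 positive, median 0.71, adjusted p = 1.7e-06; adjusted p = 0.978 with an estimated correlation). Phosphofructokinase (Pfkl) was at 1.47 ± 0.32, Pgk1 at 0.95 ± 0.25, Pdk1 at 1.05 ± 0.30 and Hif1a at 1.20 ± 0.38, with gene-level adjusted p = 1 for each. Inflammatory genes (median 0.39, adjusted p = 0.0443; Il1a 1.75 ± 0.48, Nos2 3.75 ± 1.16) and matrix proteases (adjusted p = 0.0443) were higher, and B cell markers lower (median -1.31, adjusted p = 4.08e-06; Ighm -1.36 ± 0.38). Each of these 3 lists had an adjusted p = 0.978 with an estimated correlation. Leaving out either BALB/c library ended the glycolysis (0.202 and 0.203), B cell (0.154 each) and inflammatory calls (0.511 and 0.515), and leaving out any 1 of the 4 ended the protease call (0.0822 to 0.231). Inflammatory genes turned sign without either BALB/c library, with a median of -0.18 in the C57BL/6 and 0.97 in the BALB/c pair.

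Within each strain, the 8 single pairs of libraries gave sizes without a test, since each group had 1 library. BALB/c pairs differed at more genes than C57BL/6 pairs in each population. Counts of genes with an absolute log2 ratio of at least 1 and at least 5 CPM in the higher library were 675 (276 higher in Ift88Orpk, 399 lower) in C57BL/6 and 1593 (1233 and 360) in BALB/c DBA-sorted cells. In Ly6Chi macrophages they were 169 (100 and 69) and 783 (421 and 362), in Ly6Clo macrophages 273 (216 and 57) and 994 (483 and 511), and in neutrophils 947 (731 and 216) and 2183 (1017 and 1166). Across genes, the log2 ratios of the 2 strains correlated at r = 0.04 in DBA-sorted cells, 0.21 in Ly6Chi macrophages, 0.05 in Ly6Clo macrophages and -0.23 in neutrophils, where genes are not independent replicates. In DBA-sorted cells 73 genes were higher in both strains against 17.2 for independent lists, and 58 were lower in C57BL/6 and higher in BALB/c against 21.5. In neutrophils 64 were higher in both against 55.3, while 308 were higher in C57BL/6 and lower in BALB/c against 56.4. In Ly6Chi macrophages 27 were higher in both against 2.1 and 12 lower in C57BL/6 and higher in BALB/c against 1.0, and in Ly6Clo macrophages 48 against 6.7, with 52 higher in C57BL/6 and lower in BALB/c against 7.3 and 10 the other way against 1.2. Genes lower in both strains numbered 28 against 6.1 in DBA-sorted cells, 9 against 0.9 in Ly6Chi macrophages, 9 against 1.3 in Ly6Clo macrophages and 32 against 12.4 in neutrophils.

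Gene lists gave a similar picture in these pairs, described by the median log2 ratio and its percentile among 10000 random lists of matched expression. Sinusoidal endothelial markers were at 0.38, 0.64 and 1.36 in C57BL/6 Ly6Chi macrophages, Ly6Clo macrophages and neutrophils (percentile 100 each), and at -1.36, -1.56 and -2.31 in BALB/c (percentile 0 each). Hepatocyte markers were at 0.42, 0.53 and 0.55 in C57BL/6 (percentile 100 each) and -1.36, -1.52 and -0.86 in BALB/c (percentile 0 each). In DBA-sorted cells, cholangiocyte markers were at -0.64 in C57BL/6 (percentile 0) and 0.73 in BALB/c (percentile 99.98). MHC class II genes were at -0.52 (0.24) and 1.36 (99.99), and neutrophil markers at -0.56 (2.5) and 3.22 (100). Extracellular matrix genes were at 0.65 and 1.75 (percentile 100 each), with the collagen Col1a1 at 714 CPM in wild type and 1530 CPM in Ift88Orpk of C57BL/6, and at 614 and 3420 CPM in BALB/c. Glycolysis and hypoxia genes were positive in all 8 pairs. Their medians were 0.41 and 0.38 in DBA-sorted cells, 0.22 and 0.90 in Ly6Chi macrophages, 0.22 and 0.23 in Ly6Clo macrophages, and 0.27 and 1.17 in neutrophils (C57BL/6 and BALB/c; percentiles 99.9 to 100). Cilium genes stayed within percentiles 6.4 and 94.4 in all 8 pairs. Cell cycle genes in neutrophils were at 0.93 (percentile 100) in C57BL/6 and -0.44 (1.47) in BALB/c.

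**Figure D3:**
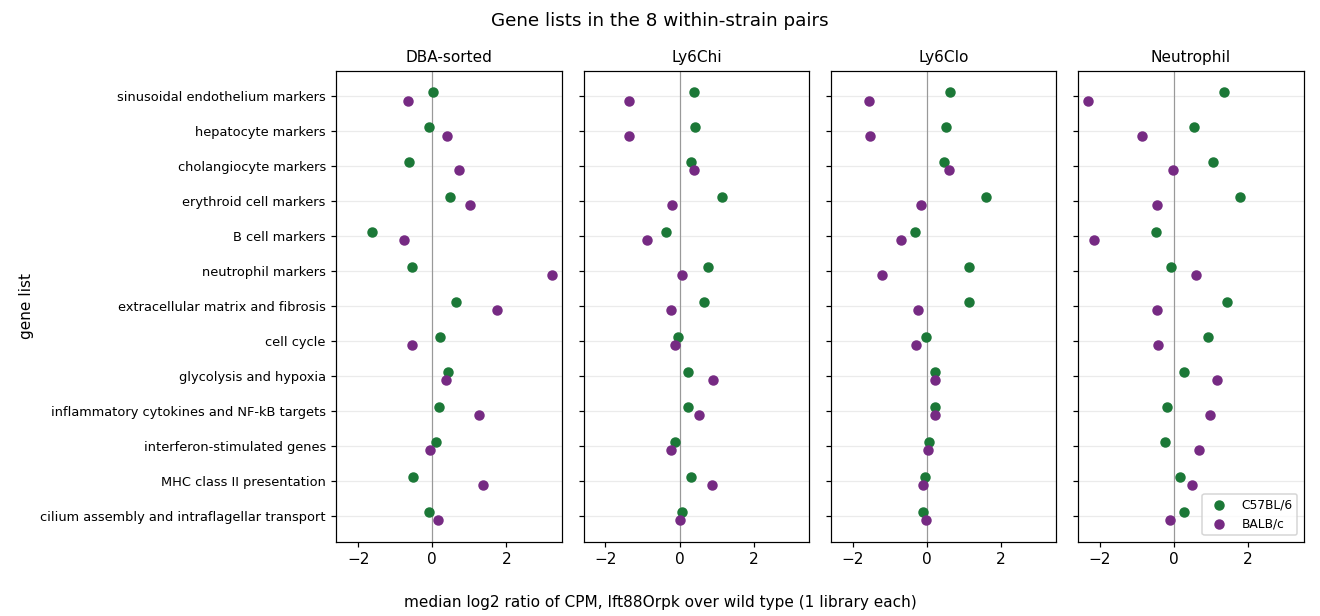
Median log2 ratio of CPM, Ift88Orpk over wild type, for 13 gene lists in the 8 within-strain pairs (1 library per group), by population and strain. Endothelial markers in leukocytes ran from -2.31 in BALB/c to 1.36 in C57BL/6.

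Genes whose ratio differed most between the strains in the DBA-sorted cells included Nrg1, Clec4e, Ccr2 and Csf3r. Nrg1, the growth factor neuregulin 1, went from 0.754 CPM in wild type to 51.8 CPM in Ift88Orpk of BALB/c (ratio 68.7, 95% counting interval 41.5 to 123) and from 19 to 8.15 CPM in C57BL/6 (0.428, 0.355 to 0.515). Serpina1e, an alpha-1 antitrypsin, had ratios of 8.74 (5.62 to 14.3) in BALB/c and 0.163 (0.15 to 0.176) in C57BL/6, and the lectin Clec4e 27.8 (17.2 to 48.1) and 0.125 (0.0376 to 0.327). Ratios were 24.3 (17.6 to 34.3) and 0.623 (0.458 to 0.846) for Ccr2, and 16.9 (13.3 to 21.8) and 0.569 (0.445 to 0.726) for the G-CSF receptor Csf3r. Pancreatic enzymes went the other way in BALB/c: Pnlip was at 28.2 CPM in wild type and 0 in Ift88Orpk (at least 199-fold lower). Cel was at 22.2 and 0.0943 CPM (0.00425, 0.000514 to 0.0155) and Ctrb1 at 39.5 and 0.895 CPM (0.0226, 0.0136 to 0.0356; 0.62, 0.529 to 0.726 in C57BL/6). Chil4, a chitinase-like protein, had a ratio of 10.4 (7.56 to 14.6) in C57BL/6 and 0 counts in both BALB/c libraries. Rprl3, a ribonuclease P RNA gene, was at 0 and 12 CPM in C57BL/6 (at least 64.7-fold higher) and 16.4 and 21 CPM in BALB/c.

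In Ly6Chi macrophages, the BALB/c ratio exceeded the C57BL/6 ratio for Jchain (1.93, 1.78 to 2.1, against 0.242, 0.228 to 0.257), Vcan (9.38, 8.67 to 10.2, against 1.37, 1.3 to 1.44), and the nuclear receptor Nr4a3 (14, 11.3 to 17.5, against 2.07, 1.68 to 2.55). The same held for Tmem119 (13.5 against 1.83) and the integrin Itga6 (11.8 against 1.88). It was below for the interferon-induced chemokine Cxcl9 (0.127, 0.109 to 0.146, against 0.974, 0.903 to 1.05) and for the hepatocyte genes Ces3a (26.2 CPM and 0, at least 136-fold lower, against 0.377), Car3 (0.0209 against 0.573) and Cyp2e1 (0.195 against 2.01). In Ly6Clo macrophages, lymphoid genes had higher BALB/c ratios: the kinase Zap70 (16.5, 12.1 to 22.9, against 0.751, 0.669 to 0.844), Klrc1 (8.94 against 0.791) and Klrc2 (7.65 against 0.582). So did Rhpn1 (7.01 against 0.541) and Vegfa (12.8, 11.1 to 14.9, against 1.28, 1.03 to 1.59). The endothelial genes Oit3 (0.185 against 2.95) and Tie1 (0.247 against 3.55), Car3 (0.0612 against 1.45), Cyp2e1 (0.16 against 2.37) and Rprl3 (0.457 against 0 and 7.96 CPM, at least 48.1-fold higher) had lower BALB/c ratios. In neutrophils, the nucleic acid sensor Zbp1 (8.18, 7.31 to 9.17, against 1.02, 0.948 to 1.09), Traf1 (8.1 against 0.972), the medium-chain fatty acid receptor Gpr84 (11.4 against 1.32), Creb5 (10.8 against 1.21) and Ms4a6c (6.71 against 0.59) had higher BALB/c ratios. Dmbt1, a mucin-like scavenger protein, went from 213 to 8.06 CPM in BALB/c (0.0378, 0.0301 to 0.0468) and from 4.26 to 12 CPM in C57BL/6 (2.82, 1.95 to 4.18). Fbn1 (0.411 against 47.5, 16.1 to 231), Cdc42ep1 (0.114 against 5.93), Oit3 (0.118 against 3.42) and Fscn1 (0.213 against 7.21) likewise had lower BALB/c ratios.

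Between the strains, Tpm3-rs7 and Ifi202b were higher and Trim12a, Ifi213 and Gvin1 lower in BALB/c in all 4 populations. The test called 64 genes in DBA-sorted cells (37 higher in BALB/c, 27 lower; 2000 at an unadjusted p below 0.05, 486 by DESeq2), and 72 in Ly6Chi macrophages (34 and 38; 1718, 517), of 21534 genes each. It called 66 in Ly6Clo macrophages (35 and 31; 1552, 394) and 288 in neutrophils (76 and 212; 2598, 928). Leaving out any 1 of the 4 libraries of a population left 47 to 55 calls in DBA-sorted cells, 4 to 11 in Ly6Chi macrophages, 5 to 7 in Ly6Clo macrophages and 123 to 133 in neutrophils. The reference genome is that of C57BL/6J, and reads lost from divergent BALB/c alleles were not measured. Pseudogene-type genes made up 12, 13, 13 and 20 of the calls in the same order, with 12, 11, 11 and 17 of them higher in BALB/c. Without pseudogene-type and ribosomal protein genes the macrophage counts were 42 and 33. The strain labels were checked on H2-Ea-ps, at 5.68 to 1410 CPM in BALB/c and at most 0.676 CPM in C57BL/6, and on Nnt, at 46 to 127 CPM against 22.1 to 44.1 CPM.

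In DBA-sorted cells, Tpm3-rs7 (ENSMUSG00000058126, chromosome 14, 113314608 to 113316754), a tropomyosin 3 related sequence, was 7.22 ± 0.37 log2 units higher in BALB/c (94.9 ± 2.84 against 0.623 ± 0.0947 CPM, n = 2 each, adjusted p = 0.000617). It was also higher in Ly6Chi macrophages (6.78 ± 0.35, adjusted p = 0.000615), Ly6Clo macrophages (6.66 ± 0.34, adjusted p = 0.000606) and neutrophils (6.79 ± 0.36, adjusted p = 0.00082). In DBA-sorted cells the antiviral genes Trim34b (10.6 against 0.0216 CPM, ratio 415, 74.2 to 16400, adjusted p = 0.00706) and Ifi202b (ENSMUSG00000026535, chromosome 1, 173962568 to 173982744; 15.9 against 0.0431 CPM, ratio 311, 85.8 to 2570, adjusted p = 0.0142) were higher. So were the pseudogene Rps2-ps10 (ratio 230, 63.4 to 1910, adjusted p = 0.0114), the mismatch repair family gene Msh5 (4.39 ± 0.37, adjusted p = 0.0038) and the enolase retrogene Eno1b (4.38 ± 0.37, adjusted p = 0.0038). Higher too were the calcium channel Cacna1a (4.32 ± 0.40, adjusted p = 0.00593), Tlr6 (4.20 ± 0.54, adjusted p = 0.022; 0.0848 with the 4 DBA-sorted libraries alone), Gbp2b (4.11 ± 0.41, adjusted p = 0.00888) and the phospholipase Pla2g7 (3.96 ± 0.27, adjusted p = 0.00132).

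Lower in BALB/c DBA-sorted cells were Ifi206 (0 against 23.6 CPM, at least 324-fold lower, adjusted p = 0.00132), the interferon-inducible GTPase Gvin1 (0 against 12.1 CPM, at least 166-fold lower, adjusted p = 0.0151), Ifi213 (C57BL/6 over BALB/c 917, 164 to 36300, adjusted p = 0.0135) and Trim12a (538, 184 to 2610, adjusted p = 0.0135). Other members of the Ifi200 cluster on chromosome 1 fell with them: Ifi204 (-3.32 ± 0.32, adjusted p = 0.00714), Ifi208 (-3.30 ± 0.37, adjusted p = 0.0135) and Ifi207 (-2.80 ± 0.31, adjusted p = 0.0135). Strip2 (-3.91 ± 0.50, adjusted p = 0.022) and the ribosomal protein genes Rpl29 (-3.40 ± 0.27, adjusted p = 0.00365) and Rpl26 (-3.20 ± 0.34, adjusted p = 0.0115) were lower as well. Among lists, inflammatory genes were higher (26 of 31 positive, adjusted p = 0.000351), as were chemokines (adjusted p = 0.0419) and cell cycle genes (adjusted p = 0.0245). Interferon-stimulated genes (5 of 39 positive, adjusted p = 0.000775) and ribosomal protein genes (median -0.31, adjusted p = 0.000724) were lower. Each of these 5 lists had an adjusted p = 0.981 with an estimated correlation. The cell cycle call was lost, with the sign turned, without the C57BL/6 wild type (0.739) or BALB/c wild type library (0.744), and the chemokine, inflammatory and interferon calls without either Ift88Orpk library (0.0684 to 0.957). Of the 20 genes named for DBA-sorted cells, 10 kept the call whichever library was left out: Trim34b, Tpm3-rs7, Msh5, Eno1b, Tlr6, Pla2g7, Ifi206, Rpl29, Ifi204 and Rpl26.

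In Ly6Chi macrophages, Ifi202b was at 175 CPM in BALB/c and 0 in C57BL/6 (at least 2110-fold higher, adjusted p = 0.0037), and Ifi44l at 129 CPM and 0 (at least 1600-fold higher, adjusted p = 0.0127). Ly6c1 (ENSMUSG00000079018, chromosome 15, 75044018 to 75048830), part of the Ly6C antigen pair, was at 111 ± 18.6 against 0.355 ± 0.0245 CPM (8.27 ± 0.64, adjusted p = 0.00431). H2-Ea-ps (10.62 ± 1.21, adjusted p = 0.0346), H2-Q1 (ratio 213, 72.4 to 1030, adjusted p = 0.044), and Rps2-ps10 (6.28 ± 0.71, adjusted p = 0.0127) were higher. So were the chromatin protein retrogene Hmga1b (5.53 ± 0.76, adjusted p = 0.0314), Ifi44 (5.20 ± 0.34, adjusted p = 0.00116) and the scavenger receptor Colec12 (5.20 ± 0.42; 383 ± 47.9 against 10.4 ± 1.51 CPM, adjusted p = 0.00319). Skint3 was at 0 against 78 CPM (at least 848-fold lower, adjusted p = 0.0127; 0.342 by DESeq2), and Trim12a had a C57BL/6 over BALB/c ratio of 2070 (372 to 81900, adjusted p = 0.0102). Vill, a villin-like protein (-7.18 ± 0.77, adjusted p = 0.0114), Gvin1 (-6.99 ± 0.63, adjusted p = 0.016), Nlrp1c-ps (-6.84 ± 0.97, adjusted p = 0.0498), Ifi213 (-6.47 ± 0.73, adjusted p = 0.0127), Nxpe4 (-5.96 ± 0.82, adjusted p = 0.0314) and the integrin Itgb2l (-5.74 ± 0.81, adjusted p = 0.0346) were lower. The cytotoxic granule genes Gzmb (-5.71 ± 0.74, adjusted p = 0.0245) and Prf1 (-5.51 ± 0.69, adjusted p = 0.0211) fell together with the T and NK cell markers (median -2.69, adjusted p = 1.64e-05; adjusted p = 0.822 with an estimated correlation).

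Other lists lower in BALB/c Ly6Chi macrophages were neutrophil markers (median -4.13, adjusted p = 7.35e-06), neutrophil granule genes (median -2.04, adjusted p = 0.000248; 0.0895 without members of other lists), and Ly6Clo monocyte markers (median -1.10, adjusted p = 0.00461). Lower as well were cell cycle genes (median -0.76, adjusted p = 0.000248), oxidative phosphorylation genes (median -0.32, adjusted p = 0.000135), ribosomal protein genes (median -0.58, adjusted p = 6.51e-12), and markers of dendritic cells (0.0166), B cells (0.0251) and Kupffer cells (0.0356). Cilium genes (0.0303) and cholesterol synthesis genes (0.012) were higher. With an estimated correlation none of these lists was called (adjusted p = 0.822 to 0.935). Kupffer cell, B cell and dendritic cell markers and cholesterol genes lost the call without either Ift88Orpk library (0.212 to 0.316), and cilium genes without either wild type library (0.161 and 0.165). Of the 20 genes named for Ly6Chi macrophages, only Tpm3-rs7 and Ifi44 kept the call whichever library was left out.

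In Ly6Clo macrophages, H2-Ea-ps was at 1360 ± 71.3 against 0.126 ± 0.134 CPM (13.59 ± 1.31, adjusted p = 0.0196), and Ifi44l at 54.8 CPM and 0 (at least 906-fold higher, adjusted p = 0.0122; 0.067 by DESeq2). Ifi202b was at 55 against 0.0467 CPM (ratio 936, 320 to 4540, adjusted p = 0.00828) and H2-Q1 at 13.7 against 0.0431 CPM (ratio 344, 94.7 to 2850, adjusted p = 0.0413). Rps2-ps10 (7.32 ± 0.74, adjusted p = 0.00976), Hmga1b (5.85 ± 0.77, adjusted p = 0.0261), Cacna1a (4.78 ± 0.43, adjusted p = 0.00637), Eno1b (4.33 ± 0.35, adjusted p = 0.00406) and Colec12 (4.33 ± 0.41, adjusted p = 0.00778) were higher. Skint3 was at 0 against 118 CPM (at least 1660-fold lower, adjusted p = 0.0105; 0.325 by DESeq2), and Vill had a C57BL/6 over BALB/c ratio of 414 (114 to 3420, adjusted p = 0.00977). Trim12a (-8.39 ± 0.90, adjusted p = 0.0105), Ifi213 (-8.30 ± 0.86, adjusted p = 0.00977), Gvin1 (-7.69 ± 0.66, adjusted p = 0.0122), and Nlrp1c-ps (-7.57 ± 0.99, adjusted p = 0.0413) were lower. So were the protease inhibitor Spint1 (-5.60 ± 0.80, adjusted p = 0.0413), Nxpe4 (-5.53 ± 0.80, adjusted p = 0.0413), Ifi206 (-4.85 ± 0.35, adjusted p = 0.00406) and Eps8l1 (-4.65 ± 0.58, adjusted p = 0.0205). Ribosomal protein genes (0 of 36 positive, median -0.77, adjusted p = 1.29e-23), oxidative phosphorylation genes (median -0.38, adjusted p = 1.12e-05) and Ly6Clo monocyte markers (median -0.70, adjusted p = 0.0129) were lower as lists. Profibrotic ligands (median 0.69, adjusted p = 0.00578), matrix proteases (0.00766), neutrophil granule genes (median 1.82, 0.00766), efferocytosis genes (0.0344) and Ly6Chi monocyte markers (0.0356) were higher. Each of these 8 lists had an adjusted p = 0.979 with an estimated correlation. Ly6Chi monocyte markers lost the call without any 1 of the 4 libraries (0.0554 to 0.0622), Ly6Clo monocyte markers without either Ift88Orpk library (0.237 and 0.241), and proteases, efferocytosis and granule genes without either wild type library (0.242 to 0.35). Of the 20 named genes, only Tpm3-rs7 kept the call whichever library was left out.

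In neutrophils, most calls were lower in BALB/c (212 of 288), among them 37 ribosomal protein genes. H2-Ea-ps (63.9 CPM and 0, at least 495-fold higher, adjusted p = 0.0275), H2-Q2 (at least 142-fold, adjusted p = 0.0204), and Ifi202b (at least 117-fold, adjusted p = 0.0111) were higher in BALB/c. So were the endocytic adaptor Sgip1 (at least 257-fold, adjusted p = 0.0164), the lectin Itln1 (25 CPM and 0, at least 205-fold, adjusted p = 0.0396; 0.367 by DESeq2) and the pseudogene Rpl10-ps2 (at least 282-fold, adjusted p = 0.0381; 0.329 by DESeq2). Further rises were those of Gbp2b (6.18 ± 0.44; 298 ± 209 against 3.72 ± 0.478 CPM, adjusted p = 0.00246), H2-Q1 (5.79 ± 0.98, adjusted p = 0.0324) and Trim34b (5.79 ± 0.58, adjusted p = 0.00665). Hmgb1-ps8 (at least 318-fold lower, adjusted p = 0.0256; 0.338 by DESeq2), Skint3 (at least 213-fold, adjusted p = 0.0129; 0.368 by DESeq2), Gvin1 (at least 132-fold, adjusted p = 0.0111) and the forkhead gene Foxd4 (C57BL/6 over BALB/c 941, 168 to 37200, adjusted p = 0.0355; 0.413 by DESeq2) were lower. Trim12a (-8.63 ± 0.89, adjusted p = 0.00701), Ifi213 (-8.23 ± 0.89, adjusted p = 0.0074), Nxpe4 (-6.74 ± 0.94, adjusted p = 0.0165) and Vill (-6.07 ± 0.72, adjusted p = 0.011) fell. So did Cyp1a1 (-5.53 ± 0.95, adjusted p = 0.0442) and the monocyte marker Vcan (-5.63 ± 1.05; 5.39 ± 6.45 against 169 ± 58.1 CPM, adjusted p = 0.0469). Vcan was lost with relative log expression factors (0.0571) and with the 5 CPM filter (0.0649). Ifi202b, Tpm3-rs7, Gbp2b, Trim34b, Skint3, Gvin1, Trim12a and Ifi213 kept the call whichever library was left out, and the other 12 named genes lost it without at least 1 library.

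Ribosomal protein genes were lower as a list in BALB/c neutrophils (0 of 36 positive, median -1.24, 19 called, 36 over the list alone, adjusted p = 6.91e-25; adjusted p = 0.92 with an estimated correlation). Rps18 (-2.36 ± 0.19, adjusted p = 0.00337), Rplp0 (-1.97 ± 0.21, adjusted p = 0.0074) and Rpl32 (-1.64 ± 0.19, adjusted p = 0.011) led it. Oxidative phosphorylation genes were lower (2 of 36 positive, median -0.56, adjusted p = 1.49e-07; adjusted p = 0.92 with an estimated correlation), with 11 called over the list alone. Monocyte transcripts moved with these lists: in C57BL/6 neutrophils Ccr2 was at 31.8% of its level in Ly6Chi macrophages of that strain and Vcan at 78.2%, and in BALB/c neutrophils at 4.19% and 2.81%. Interferon-stimulated genes moved in both directions in neutrophils, with Ifi204 (-4.08 ± 0.33, adjusted p = 0.00337), Oasl2 (-2.93 ± 0.33, adjusted p = 0.00923) and Ifit3 (-1.55 ± 0.26, adjusted p = 0.0311) lower and Ifi44l called higher (adjusted p = 0.0226).

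Direct tests of whether effects differed between groups called 0 of 21534 genes each. For the strain by genotype term shared by the 4 populations, 1202 genes had an unadjusted p below 0.05 and DESeq2 called 227; without the DBA-sorted libraries the test called 116. For the strain by macrophage type term the counts were 400 and 28, and for the genotype by macrophage type term 144 and 0. With the 8 macrophage libraries alone these last terms gave 168 and 6 genes, and upper-quartile factors gave 4 for the strain by macrophage type term. The strongest list in the strain by genotype term was sinusoidal endothelium (0 of 11 positive, median -2.03, 10 called over the list alone, adjusted p = 1.48e-09; adjusted p = 0.919 with an estimated correlation). Cell cycle genes followed (0 of 40 positive, median -0.73, adjusted p = 2.26e-09; adjusted p = 0.919 with an estimated correlation).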

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

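The tests of explanations here were chosen after the results were seen, and the tests of differences between groups were planned. Adjusted p values below are camera's with the preset correlation; with an estimated correlation no list was called (adjusted p = 0.919 for the strain by genotype term, 0.913 for strain by macrophage type and 0.952 for genotype by macrophage type).

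For 11 lists the genotype effect differed between the strains by the shared strain by genotype term, where a negative median means a lower Ift88Orpk effect in BALB/c. The term takes the 4 populations as replicates, and with 1 pool per strain and genotype that may share mice, it does not part strain effects from differences between the 4 sets of mice. Sinusoidal endothelial markers had an adjusted p = 1.48e-09 (0 of 11 positive, median -2.03) and cell cycle genes 2.26e-09 (0 of 40, -0.73). Markers of Ly6Chi monocytes had 4.58e-05 (11 of 11, 1.17), of hepatocytes 0.000118 (2 of 12, -1.27), of Kupffer cells 0.000118 (0 of 11, -1.24), of erythroid cells 0.000638 (1 of 8, -2.26) and of stellate cells and fibroblasts 0.0292 (1 of 11, -1.21). Extracellular matrix genes had 0.000118 (8 of 35, -1.23), MHC class II genes 0.000537 (12 of 13, 0.72), inflammatory genes 0.000767 (24 of 31, 0.39) and glycolysis genes 0.0036 (28 of 31, 0.34). The DBA-sorted pairs went against the shared sign for 5 of these lists, with BALB/c minus C57BL/6 medians of 1.37 for stellate, 1.20 for matrix, 0.57 for hepatocyte, 0.23 for erythroid and 0.14 for Kupffer cell genes, as did Ly6Clo pairs for inflammatory genes (-0.11). Medians lay near 0 for glycolysis genes in DBA-sorted (-0.01) and Ly6Clo (0.07), MHC class II genes in Ly6Clo (0.02) and cell cycle genes in Ly6Chi pairs (0.01). The call was lost without the neutrophil libraries for stellate (0.764), erythroid (0.0529), matrix and inflammatory (0.0831 each) and glycolysis lists (0.252). It was lost without the Ly6Clo libraries for stellate markers (0.0971), without the Ly6Chi libraries for glycolysis genes (0.192), and without the DBA-sorted libraries for MHC class II genes (0.149).

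For 7 lists the strain effect differed between Ly6Chi and Ly6Clo macrophages, where a negative median means a lower BALB/c effect in Ly6Chi cells. Neutrophil granule genes had an adjusted p = 1.47e-08 (3 of 20 positive, median -4.31), neutrophil markers 2.08e-06 (2 of 12, -4.26), cell cycle genes 0.000812 (8 of 40, -0.60), interferon-stimulated genes 0.00103 (31 of 39, 0.30), ribosomal protein genes 0.00116 (34 of 36, 0.21), T and NK cell markers 0.00127 (3 of 11, -2.36) and alternative activation genes 0.00212 (5 of 26, -1.14). For 2 lists the genotype effect differed between the macrophage types: immediate early genes 0.00604 (26 of 33, 0.23) and glycolysis genes 0.00639 (25 of 31, 0.34). Of these 9 lists only the granule genes kept the call whichever macrophage library was left out. Neutrophil markers lost it without the C57BL/6 (0.07) or BALB/c (0.0601) wild type Ly6Clo library. Cell cycle (0.924 and 0.932), interferon (0.367 and 0.37), alternative activation (0.0632 and 0.064) and T and NK lists (0.0584 and 0.0583) lost it without either wild type Ly6Chi library. Without either Ift88Orpk Ly6Clo library the cell cycle (0.371 and 0.369), interferon and T and NK lists (0.145 and 0.144 each) lost it as well. Without either wild type Ly6Clo library the alternative activation (0.106 and 0.0999) and ribosomal lists (0.231 and 0.18) lost it, and without either Ift88Orpk Ly6Chi library the ribosomal list did (0.259 and 0.257). The genotype by type calls were lost without any BALB/c macrophage library (glycolysis 0.27 to 0.74, immediate early genes 0.165 to 0.619).

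Endothelial markers had a median log2 ratio of Ift88Orpk over wild type above 0 in the 4 C57BL/6 pairs and below 0 in the 4 BALB/c pairs, and the medians of the pairs differed by -1.97, a difference of pairs that was not tested. In the 6 leukocyte pairs the endothelial and hepatocyte transcripts may be RNA carried over from other liver cells, which a gate on leukocyte antigens would reduce. Of the 100 most abundant genes enriched in the DBA-sorted libraries and outside the marker lists, 64, 83 and 96% moved up in C57BL/6 Ly6Chi, Ly6Clo and neutrophil pairs and 80, 84 and 98% moved down in BALB/c pairs, and the lowest, 64%, lay between the bounds set for and against. A different balance of the sexes could also part the pools: Xist log2 ratios were -3.06, -1.78 and -2.29 in C57BL/6 and 1.80, 2.02 and -0.09 in BALB/c, and the smallest, 0.09 in size, left this undecided. Carry-over and sex balance cannot be told apart with 1 pool per group, and the strain by genotype term, which was called for these markers, does not part either from an effect of strain on the Ift88Orpk phenotype.

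Ribosomal protein genes were lower in BALB/c than in C57BL/6 neutrophils, and counting near-identical copies with each gene left the median at -1.18 (genes alone -1.23), which argues against unique reads lost to copies but not against reads dropped as multiply aligned. Gm26917 rose by 1.0 log2 units in BALB/c neutrophils. In DBA-sorted, Ly6Chi and Ly6Clo cells it rose by 2.71, 3.18 and 3.75, and the ribosomal falls grew in that order (-0.3, -0.57 and -0.76). Monocyte RNA in the C57BL/6 neutrophil libraries, which a Ly6G gate would remove, is a candidate source. Its 11 markers had a median of 75.5% of their Ly6Chi level (12.3% in BALB/c) against 30.2% needed. Of these, Hp and Mgst1 are also high in BALB/c neutrophils. Over 100 abundant Ly6Chi genes the median was 32.7% (quartiles 26.5 to 37.6%). This and the lowest marker, Plac8 (29.2%), lay near 30.2%. C57BL/6 neutrophil markers had a median log2 ratio over BALB/c of -0.26 (SD 0.46). Monocyte RNA leaves the macrophage falls unexplained, and differences of library or strain stay open as untested.

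Matrix genes were higher in the Ift88Orpk DBA-sorted libraries of both strains. RNA from quiescent stellate cells as the sole source was argued against in these pairs. The 6 stellate markers outside the matrix list had medians of -0.52 (SD 0.9) in C57BL/6 and 0.03 (SD 1.41) in BALB/c. The 35 matrix genes had 0.65 and 1.75 (1-sided permutation p = 0.00017 and 0.0126). These p values shuffle genes within 1 pair of libraries and do not cover the spread between pools. The markers split: Pdgfrb rose like the matrix genes (1.29 and 2.93), and Des was at -0.59 and 0.85. Lrat, Reln, Ecm1 and Colec11 lay between -1.23 and -0.21 in C57BL/6 and between -0.83 and 0.23 in BALB/c. A smaller share of endothelial RNA was argued against as the whole cause in C57BL/6 by an endothelial median of 0.01 in that pair. In the BALB/c pair the endothelial median was -0.66, as the explanation needs. Neutrophil and cholangiocyte markers moved apart there (2-sided permutation p = 3e-05 over the genes of 1 pair). A separate rise of neutrophil RNA would part them too, so this test cannot decide the explanation in BALB/c. An earlier bound, that another marker list fall in all its members in both strains, had left the endothelial share undecided, with B cell markers lower in 8 of 8 and 7 of 8. Activated stellate cells, portal fibroblasts and a change in the sorted cells with genotype may each be the source and were not tested.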

How the results depend on the processing

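The fits without Gm26917, Lars2 and mitochondrial genes, the fits without pseudogene-type and ribosomal protein genes and the test of other splits were chosen after the results were seen; the other alternatives were planned. The labels give no replicate numbers, so libraries were paired only by the block of strain and genotype in the Ly6Chi against Ly6Clo comparison. With 1 pool per group, spread between animals was not measured.

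Of the 12 counts of called genes, 7 stayed within 1.5 times their value whichever library, combination or population was left out; the lone library left in a group was then assumed to vary like the others. The ranges were 2720 to 3390 for Ly6Chi against Ly6Clo macrophages, 0 to 48 for genotype in DBA-sorted cells, 47 to 55 for strain in DBA-sorted cells, 4 to 11 in Ly6Chi macrophages, 5 to 7 in Ly6Clo macrophages and 123 to 133 in neutrophils, and 0 to 116 for strain by genotype. For genotype in the 3 leukocyte populations and for both macrophage type terms they were 0 to 0. Relative log expression factors, the 5 CPM filter and removal of Gm26917, Lars2 and mitochondrial genes moved none of the 12 counts by over 1.5 times.

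DESeq2 called 83 genes for genotype in DBA-sorted cells, 3 in Ly6Chi macrophages, 11 in Ly6Clo macrophages and 26 in neutrophils, 486, 517, 394 and 928 for strain in the same order, 227 for strain by genotype and 28 for strain by macrophage type. Ly6Chi against Ly6Clo gave 1467 with all 16 libraries and 1861 without the block. With only the 4 libraries of a population, genotype in DBA-sorted cells gave 1, and strain gave 359, 158 and 149 in Ly6Chi macrophages, Ly6Clo macrophages and neutrophils. An added strain by genotype term gave 1 for genotype in Ly6Clo macrophages. Without a filter, strain gave 124 and 103 in Ly6Chi and Ly6Clo macrophages, and without pseudogene-type and ribosomal protein genes 42 and 33, where fewer genes were tested. The 3 leukocyte populations gave 116 for strain by genotype, the 8 macrophage libraries 168 for strain by macrophage type and 6 for genotype by macrophage type, and upper-quartile factors 4 for strain by macrophage type. The cause of these changes was not tested.

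Counts of single pairs depended on pseudocount and minimum. In C57BL/6, with a pseudocount of 5 CPM, a minimum of 20 CPM and no minimum, they were 162, 167 and 1860 in DBA-sorted cells, 75, 50 and 550 in Ly6Chi macrophages, 104, 85 and 705 in Ly6Clo macrophages and 333, 274 and 2320 in neutrophils. In BALB/c they were 768, 549 and 3598, then 388, 343 and 1418, then 522, 411 and 1651, then 1212, 1095 and 3593. A pseudocount of 0.25 CPM and the other scalings moved none of the 8 by over 1.5 times.

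Of 105 list calls, 0 held with an estimated correlation and 13 with fry, 102 with relative log expression scaling, 103 without shared members, and 40 whichever library was left out. Of 104 named genes, 96 kept the call with DESeq2, 103 with relative log expression factors, 104 with upper-quartile factors, 82 with the 5 CPM filter, 104 without a filter and 44 whichever library was left out. Without pseudogene-type and ribosomal protein genes 61 of 68 kept it.

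The sign turned in 14 leave-one-out values of 7 lists, none of them then called. For genotype in DBA-sorted cells the adjusted p was 0.29 and 0.272 for neutrophil markers, 0.469 and 0.451 for Ly6Chi monocyte markers and 0.497 and 0.474 for granule genes without the BALB/c wild type or Ift88Orpk library. Over the 4 libraries left out in turn, these lists ranged from 8.64e-08 to 0.29, from 5.83e-05 to 0.469 and from 3.14e-10 to 0.497. In Ly6Clo macrophages the adjusted p was 0.126 and 0.121 for hepatocyte markers without those of BALB/c (range 2.31e-05 to 0.126) and 0.782 and 0.762 for erythroid markers without those of C57BL/6 (0.00492 to 0.782). In neutrophils it was 0.515 and 0.511 for inflammatory genes without those of BALB/c (0.000307 to 0.515). For strain in DBA-sorted cells it was 0.739 and 0.744 for cell cycle genes without the C57BL/6 or BALB/c wild type library (0.00013 to 0.744). Why the sign turned was not tested beyond the pairs of each strain.

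Of the 35 splits of the 8 macrophage libraries into groups of 4, only 1, the real split, called as many genes without a block (1861). The highest other was 757, the split by strain. Ranking first of 35 is the most extreme result this test can give. The libraries differ by strain and genotype and are not freely exchangeable, so the test does not exclude chance. Of the 8 splits that part the libraries of all 4 combinations, as the block does, the other 7 called 0 genes, and 8 splits are too few for a share under 0.05.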

Other observations

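All values here come from single libraries or pairs of libraries, and those to describe were chosen after they were seen; no test was run on them. In the DBA-sorted cells, targets of YAP and TEAD, the effectors of the Hippo pathway, had a median log2 ratio of Ift88Orpk over wild type of -0.21 in C57BL/6 (percentile 0.48 of random lists) and 0.80 in BALB/c (percentile 100). Bile secretion and transport genes were at -0.31 (percentile 0.21) and 0.37 (98.02), cholesterol and fatty acid synthesis genes at -0.23 (0.11) and 0.39 (99.9), and chemokines and myeloid growth factors at 0.08 (77.59) and 0.85 (99.91). Hepatorenal cystic disease genes were at -0.12 (4.34) and 0.27 (96.96). Stellate cell and fibroblast markers were at -0.04 (21.97) in C57BL/6 and 2.37 (100) in BALB/c, and the 6 of them outside the matrix list at -0.52 and 0.03.

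In the leukocyte pairs, extracellular matrix genes had medians of 0.67, 1.13 and 1.42 in C57BL/6 Ly6Chi macrophages, Ly6Clo macrophages and neutrophils (percentile 100 each), and of -0.24, -0.24 and -0.46 in BALB/c (percentiles 2.33, 1.62 and 0.02). Kupffer cell markers in Ly6Clo macrophages and neutrophils were at 0.42 and 0.77 in C57BL/6 (99.79 and 100) and at -0.99 and -1.14 in BALB/c (0 each). Efferocytosis and complement genes were at 0.96 and 0.35 in Ly6Clo macrophages (C57BL/6 and BALB/c, percentile 100 each), and at 0.72 (100) and -0.80 (0) in neutrophils. Interferon-stimulated genes in neutrophils were at -0.23 (0.69) in C57BL/6 and 0.67 (99.98) in BALB/c. Markers of T and NK cells in Ly6Clo macrophages were at -0.19 (2.08) and 2.32 (100). Erythroid markers were at 1.14, 1.60 and 1.78 in the C57BL/6 leukocyte pairs (percentile 100 each) and at -0.19, -0.15 and -0.47 in BALB/c (25.19, 29.76 and 8.5).

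The labels state equal numbers of each sex in the pools. Xist, expressed from the inactive X chromosome of females, was at 842 and 240 CPM in the C57BL/6 wild type and Ift88Orpk DBA-sorted libraries and at 173 and 655 CPM in those of BALB/c. In the same order it was at 1180, 141, 136 and 474 CPM in Ly6Chi macrophages, 1160, 336, 190 and 773 CPM in Ly6Clo macrophages and 559, 113, 192 and 181 CPM in neutrophils. The Y-linked Ddx3y was at 22.5, 62.9, 35.6 and 31.3 CPM in DBA-sorted cells, 36.9, 88.5, 61.1 and 71.5 CPM in Ly6Chi macrophages, 35.8, 88.0, 98.1 and 49.0 CPM in Ly6Clo macrophages and 33.2, 164, 98.9 and 278 CPM in neutrophils.

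Gm26917, a predicted gene on chromosome 17, took 11400 to 25000 CPM in the 8 C57BL/6 libraries and 23500 to 203000 CPM in the 8 BALB/c libraries. Lars2 ran from 18.6 CPM in C57BL/6 wild type Ly6Clo macrophages to 4460 CPM in BALB/c wild type DBA-sorted cells.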
